A study of Mus musculus with 9 samples.

How the data were processed

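Gene expression was measured on Affymetrix whole-transcript arrays in neutrophils sorted from mouse blood, 9 arrays in 3 groups of 3. Control neutrophils were donor cells recovered 10 min after adoptive transfer into a host, and aged neutrophils were recovered 6 h after transfer. Activated neutrophils came from mice given 0.5 µg of tumour necrosis factor alpha (TNF) 2 h earlier, and the labels do not describe these cells as transferred, although they name the CD45.1 allele, the mark of donor cells, for every sample. Per the labels' protocols, 2000 cells per sample were collected by flow cytometry, RNA was amplified with a kit made for direct amplification from few cells, and the product was labelled with biotin. The amplification step precedes every value, so differences in its yield between samples are part of the spread between arrays.

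The values used were probe-set intensities deposited by the authors on a linear scale. They were made with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes, which give no version. The array images were not used here. The design written before the data were examined assumed log2 values, but the deposited values ran from 16.1 to 11850, so their log2 was taken before limma was applied. Quantile normalization gives every array nearly the same distribution, and the median intensity of the arrays lay between 188.5 and 196.6. It hides any change in the total amount of RNA per cell, and the brightest transcripts are compressed near the top of the range.

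The table held 24679 rows. The annotation paired 21354 rows with 1 gene symbol, 1275 with several and 2050 with none, and only rows with 1 symbol entered the tests. Of these, 21277 were matched by gene identifier to a RefSeq table of assembly GRCm38.p6, 77 kept the symbol of the annotation, and 0 symbols changed. The 893 genes with several probe sets were represented by the probe set with the highest mean over the 9 arrays, which left 19751 genes. No coordinates were printed because the build of the array annotation was not given in the sources used here. The 1194 olfactory and vomeronasal receptor genes, which neutrophils are not known to use, served as a guide to background. Their 95th percentile was a log2 value of 7.87, an intensity of 234.6, and 8017 genes (40.6%) had a mean over the 9 arrays above it. For a named gene past the threshold with a group mean under this level, the size of the change has only a lower bound, written as at least N-fold. It sets the brighter mean against the dimmer arrays, each taken at the level or at its own value if higher. The bound allows for background alone and not for the spread between arrays. It is no confidence limit, and the true change may be smaller.

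Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over the 19751 genes, threshold 0.05). All 9 arrays were fitted in 1 model with a mean per group, so that the groups shared 1 estimate of the spread. The residual degrees of freedom were 6 and the prior added 1.78. Log2 fold changes are given with the standard error (SE) of that model, and folds with 95% intervals. The number of arrays limits the precision. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

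Before the data were examined, 19 functional gene lists and 10 lists of cell type markers were fixed, together 512 entries, of which 452 were measured among the rows with 1 gene. The remaining entries were not analysed here. Lists were tested with camera of limma at its preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 29 lists of a comparison. Camera with an estimated correlation and fry, which asks only whether the genes of a list move on balance one way, were run beside it. Beside counts over all genes, the text gives the count adjusted over the list alone.

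The genes named in the text followed a rule set beforehand. It took the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold whose arrays did not overlap between groups. Unnamed gene models, small RNA genes, antigen receptor segments and odorant receptors were passed over. Where fewer than 5 genes passed in a direction, the 5 with the largest change at an unadjusted p under 0.01 were named as not past the threshold. The rule added up to 4 members with the smallest p of each functional list and a fixed panel of surface molecules. Other list members are named only inside a count of called genes, and genes chosen after their values were seen are said to be so.

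The steps were tested on simulated data with the real means and spreads of 19751 genes. For aged against control, limma recovered 60% of genes changed 1.5-fold, 74% at 2-fold, 94% at 4-fold and 94% at 8-fold, with 10 unchanged genes called. For activated against control the shares were 56%, 78%, 88% and 96%, with 11 unchanged genes called. The changed genes were drawn from all genes, most of them under the receptor level, and took the full fold. The median SD within a group was 0.085 to 0.105 over all genes and 0.163 to 0.178 for genes above that level. The shares may therefore be too high for brighter genes, and they do not show that changes of these sizes were absent where none was called. A list shifted by 0.5 on the log2 scale was recovered in both comparisons, and 0 of the 28 other lists were called. The simulated genes varied independently, so this says nothing about false list calls that arise from correlation between genes. The alternatives tried were filters on dim genes, repeated quantile normalization, centring of arrays, array weights, the mean of a gene's probe sets, a fit of only the compared groups, no intensity trend, a fold change minimum, every row of the table, a block for the replicate number and leaving out each array. A filter at the receptor level and a robust variance model were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.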

Results

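The data described how the transcripts of circulating neutrophils differed after 6 h in the blood of a host (aged cells) and 2 h after TNF (activated cells), each against donor cells 10 min after transfer. Every group had 3 arrays. Mean correlations of log2 values across genes were 0.963 within control, 0.957 within aged and 0.972 within activated arrays. They were 0.958 between aged and control arrays, 0.940 between activated and control arrays and 0.934 between activated and aged arrays. The pooled SD between arrays of a group was 0.291 on the log2 scale in control, 0.311 in aged and 0.254 in activated neutrophils.

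The first comparison asked how time in the circulation changed neutrophil transcripts. In aged neutrophils 0 of 19751 genes passed limma's threshold against control. In the main tests, calls came only from lists of genes, by camera at its preset correlation. Transcripts of secondary and tertiary granule proteins, the antimicrobial and matrix-degrading cargo loaded late in neutrophil maturation, were lower as a list, with 12 of 16 members below 0 and a median log2 fold change of -0.19. Glycolysis and hypoxia genes were lower (16 of 21 below 0, median -0.14), and surface molecules tied to neutrophil ageing by earlier work were higher (8 of 11 above 0, median 0.15). All 3 lists passed camera with Benjamini-Hochberg adjustment, at adjusted p = 0.00027, 0.00724 and 0.0084, and each had adjusted p = 0.125 with an estimated correlation. The estimated correlations were 0.01, 0.001 and -0.007, not above the preset 0.01, so correlation between genes does not account for the higher p. By fry the 3 lists had adjusted p = 0.0451, 0.113 and 0.113.

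Among the granule genes, Ngp (neutrophilic granule protein) had a log2 fold change of -2.35 ± 0.33 (SE, n = 3 per group) and Mmp8, a collagenase, one of -0.64 ± 0.09. Aged replicate 3 of Ngp lay under the receptor level, so its size is measured partly against background. Lyz2 (lysozyme) had -0.80 ± 0.25 and Lcn2 (lipocalin 2, which binds iron carriers of bacteria) had -0.53 ± 0.21. Over all genes 0 of the 16 members passed, and adjusted over the list alone 2 were lower, Mmp8 and Ngp. In the glycolysis and hypoxia list Slc16a3, a lactate exporter, had -0.55 ± 0.16, the glucose transporter Slc2a3 had -0.28 ± 0.08, and 0 of 21 passed over all genes or adjusted over the list alone. Bnip3 had -0.83 ± 0.40, while a second probe set of it, nearly as bright, had -0.21. Egln3, an oxygen sensor, lay the other way at 1.02 ± 0.54, which without aged replicate 1 was 0.32. Among the ageing markers the integrin subunits Itga4 and Itgax had 0.45 ± 0.15 and 0.46 ± 0.21, and Icam1, a ligand of integrins, 0.45 ± 0.18; 0 of 11 passed over all genes or adjusted over the list alone.

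The fixed panel of surface molecules showed small differences in aged cells, none past the threshold. Cxcr4, the receptor that draws neutrophils back to the bone marrow, had a log2 fold change of -0.01 ± 0.19, with a 95% interval from -0.45 to 0.42. Cxcr2, which receives the signals for release from marrow, had 0.14 ± 0.07, and the integrin subunit Itgam 0.17 ± 0.11. Tlr4, the receptor for lipopolysaccharide, had 0.22 ± 0.16, Cd47 had 0.15 ± 0.10 and Cd44 had -0.04 ± 0.11. Another probe set of Cd47 had -0.05.

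The largest single differences in aged cells did not pass limma's test after Benjamini-Hochberg adjustment. Ly6g, the antigen used to recognise mouse neutrophils and a member of a family of similar genes, had a log2 fold change of -3.15 ± 0.63 (adjusted p = 0.53), and its control arrays spread with an SD of 1.27. Mcts2 had -3.07 ± 0.65, Ceacam10 -2.79 ± 0.59 and Ptgs2, the inducible cyclooxygenase, -2.16 ± 0.25 (adjusted p = 0.1). The aged arrays of Ceacam10 were uneven, at 9.26, 6.92 and 7.77. Ly6g, Mcts2 and Ceacam10 each had an aged array under the receptor level, so their sizes are measured partly against background. Rnase6, with control replicate 1 under the receptor level, had 1.46 ± 0.38 and Ltb (lymphotoxin beta) 1.40 ± 0.38. The control means of Commd6, Ppp1r11, a phosphatase inhibitor, and Rnmt lay under the receptor level; counted from that level their aged means were higher by 2.77, 1.78 and 0.04 on the log2 scale, with Ppp1r11 at the smallest adjusted p of all genes, 0.079.

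The other 16 functional lists did not pass in aged cells, with camera adjusted p of 0.398 or higher. They covered adhesion, Toll-like and NOD-like receptors, NF-kB, immediate early genes, cytokines, chemoattractant receptors, primary granules, NADPH oxidase, interferon, circadian clock, apoptosis, glucocorticoid response, oxidative phosphorylation, cell cycle, heat shock and ribosomal proteins. Adjusted over the list alone, Sod2 and Cflar were lower in the NF-kB list, and Birc2 was higher and Cflar lower in the apoptosis list, with 0 in the other 14 lists and 0 of any past the threshold over all genes. The probe sets of Cflar, an inhibitor of death receptor signalling, did not share 1 direction. Birc2 had 1.04 on the probe set used and 0.22 on another, whose mean of 7.90 lay near the receptor level. Of the 10 marker lists 0 passed; in the neutrophil list 4 of 10 members were lower adjusted over the list alone (Il1r2, Ly6g, Retnlg, Trem1). That list, at camera adjusted p = 0.123, was lower past the threshold with repeated quantile normalization (0.00655) and without control replicate 3 (0.0263).

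By limma 853 genes (4.32%) had an unadjusted p under 0.05 between aged and control cells, and 7.21% of genes had arrays that did not overlap between groups, where chance gives 10%. The ageing markers lost their call without control replicate 1 or aged replicate 2 (highest adjusted p = 0.169) and the glycolysis and hypoxia list without control replicate 2 or aged replicate 2 (highest 0.117). Without the genes below the median intensity, 6 genes passed.

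**Figure D1:**
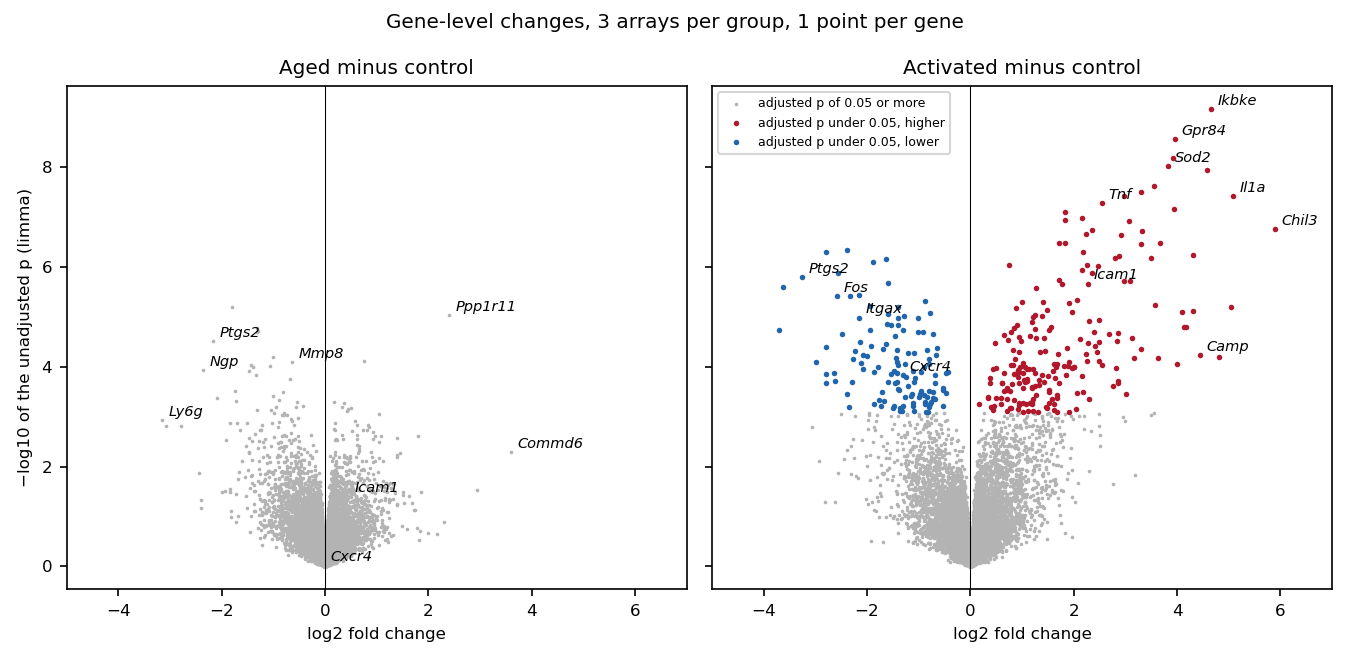
Log2 fold change (x axis) against -log10 of limma's unadjusted p (y axis) for each gene, aged minus control on the left and activated minus control on the right, with genes past the adjusted threshold in colour. On the left 0 genes were past it, and on the right 205 were higher and 121 lower.

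The second comparison set neutrophils of mice given TNF against control cells; the control cells had been transferred, and whether the activated cells were is not stated, although the labels name the donor allele CD45.1 for them too, so TNF and transfer cannot be told apart in any of its values. Activated cells had more transcript from secondary and tertiary granule genes and from the NF-kB pathway, and less of the homing receptor Cxcr4. Saa3, an acute-phase protein, was at least 23.9-fold higher (n = 3 per group), Chil3, a chitinase-like granule protein, at least 23.6-fold, and Il1a, an alarm cytokine, at least 7.37-fold. These are bounds because the control means lay under the receptor level, which was then taken in place of each lower control value. In all, 326 genes passed limma's threshold after Benjamini-Hochberg adjustment, 205 higher and 121 lower, and 240 of them differed by more than 2-fold.

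Secondary and tertiary granule genes rose together: 9 of 16 were higher and 0 lower over all genes, and 13 were higher adjusted over the list alone. The mean log2 fold change was 1.93, with camera adjusted p = 1.88e-21, and adjusted p = 0.000897 with an estimated correlation. Camp, the cathelicidin precursor, rose by 4.44 ± 0.57 on the log2 scale, with its control mean raised by control replicate 3 (5.22 without it, measured against background, since the other 2 control arrays lay under the receptor level). The iron-binding Ltf (lactoferrin) rose at least 13.7-fold, Itgb2l at least 8.42-fold and the membrane protease Mmp25 by 1.91 ± 0.17 on the log2 scale. Cd177, a neutrophil surface glycoprotein, rose by 2.49 ± 0.29. The primary granule list did not pass (camera adjusted p = 0.301, median -0.03, mean 0.70): 2 of 8 rose, the protease inhibitor Serpinb1a at least 10.6-fold and the protease activator Ctsc, with both group means under the receptor level, also 2 adjusted over the list alone. Elane (neutrophil elastase) had -0.09 ± 0.09, with its activated mean under the receptor level.

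Of the NF-kB pathway and feedback list, 11 of 26 members rose and 0 fell, and 16 were higher adjusted over the list alone. The list's median was 0.99, with camera adjusted p = 3.45e-21, and adjusted p = 0.000897 with an estimated correlation. Ikbke, a kinase of the pathway, rose at least 19.4-fold, the subunit Relb at least 3.21-fold and the adaptor Traf1 at least 1.78-fold, with control means under the receptor level, and Sod2, the mitochondrial superoxide dismutase, rose 14.2-fold (95% interval 11.2 to 18.2). Control replicate 1 of Sod2 lay under that level, so its fold is measured partly against background. The Toll-like and NOD-like receptor list was higher (camera adjusted p = 1.07e-05, and adjusted p = 0.0151 with an estimated correlation). Of its 27 members 3 rose, the inflammasome sensor Nlrc4 at least 3.39-fold, the ligase Traf6 by 1.68 ± 0.29 and Casp4, a protease that senses lipopolysaccharide, by 1.19 ± 0.21; adjusted over the list alone 9 were higher and 1 lower. Control replicate 1 of Traf6 lay under the receptor level, so its size is measured partly against background. Cd14 had 2.20 ± 0.47 without passing over all genes.

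In the NADPH oxidase list, the enzyme complex behind the respiratory burst, Cybb rose by 2.77 ± 0.44 and Cyba by 0.85 ± 0.15, 2 of 8 members, with 4 higher adjusted over the list alone. Its camera adjusted p was 0.000624, with adjusted p = 0.0512 with an estimated correlation. In the apoptosis and survival list 1 of 20 rose, Birc3, an inhibitor of apoptosis, by 1.01 ± 0.19, and 7 were higher adjusted over the list alone. Its camera adjusted p was 0.000325, with adjusted p = 0.0551 with an estimated correlation. The members with the smallest p also included Casp8 (1.39 ± 0.27), which promotes death, and Bcl2l1 (1.73 ± 0.41), which prevents it, neither past the threshold. Control replicate 2 of Bcl2l1 lay under the receptor level.

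Among cytokines and chemokines 4 of 26 rose and 1 fell, and 6 were higher and 3 lower adjusted over the list alone, while the list did not pass (camera adjusted p = 0.0583), though it did in 2 of the 9 fits that left out an array. Besides Il1a, Tnf itself rose 5.88-fold (95% interval 4.8 to 7.2) and Il1rn, the antagonist of the interleukin 1 receptor, by 0.71 ± 0.11 on the log2 scale; Cxcl2 was the other member that rose. Ccl6 fell by 0.66 ± 0.08. In the list of chemoattractant and lipid mediator receptors (camera adjusted p = 0.0404, and adjusted p = 0.18 with an estimated correlation) Gpr84, a receptor for medium-chain fatty acids, rose at least 12.3-fold and Cxcr4 fell by 1.30 ± 0.19. Of its 19 members, 4 were higher and 1 lower adjusted over the list alone.

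Immediate early and MAPK feedback genes were lower as a list (camera adjusted p = 0.0427, and adjusted p = 0.311 with an estimated correlation). Of 32 members 3 fell, the transcription factors Atf3 (log2 fold change -2.99 ± 0.40) and Fos (by at least 2.20 on the log2 scale) and the phosphatase Dusp6 (-1.21 ± 0.19). Dusp16, a phosphatase of stress kinases, rose by 1.47 ± 0.27, and 3 were higher and 6 lower adjusted over the list alone. Among all genes the largest decreases included those of Ptgs2 (-3.25 ± 0.25), Cd101, a surface protein of mature neutrophils (-2.80 ± 0.43), Pctp (-2.79 ± 0.34), the kinase Sik1 (-2.79 ± 0.19), the lysosomal lipase Lipa (-2.79 ± 0.40) and Rasa3 (-2.64 ± 0.38). Coq10b was at least 6.40-fold, Prr5l at least 3.61-fold and Tas2r143, annotated as a bitter taste receptor, at least 9.93-fold lower; whether the probes of Tas2r143 read that gene or an overlapping transcript is uncertain. The activated means of Coq10b, Fos, Prr5l and Tas2r143 lay under the receptor level. Activated replicates 1 and 3 of Pctp and Lipa and activated replicate 1 of Cd101 lay under it too, so the sizes given for these genes are measured partly against background.

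The ageing surface markers did not pass as a list (camera adjusted p = 0.593), since their members went both ways. Icam1 rose 4.84-fold (95% interval 3.6 to 6.5), whereas Itgax (-2.15 ± 0.22), Cxcr4 (-1.30 ± 0.19) and Itga4 (-0.87 ± 0.15) fell, and adjusted over the list alone 3 were higher and 4 lower of 11. Of the rest of the panel, Cxcr2 had 0.03 ± 0.07, Itgam -0.01 ± 0.11, Tlr4 0.63 ± 0.16, Cd47 0.34 ± 0.10 and Cd44 -0.30 ± 0.11, none past the threshold over all genes. In the adhesion list (camera adjusted p = 0.79) 5 of 31 rose, among them Itgb1 by 1.70 ± 0.21, and 3 fell, with 6 higher and 4 lower adjusted over the list alone.

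The remaining lists did not pass. Interferon response genes had camera adjusted p = 0.937, with Gbp5 higher (at least 10.6-fold) and Ifitm1 (-0.68 ± 0.10) and Oasl2 (-0.73 ± 0.12) lower, and 2 higher and 3 lower of 29 adjusted over the list alone. The circadian list (adjusted p = 0.754) held 1 gene that rose, Bhlhe40, and glycolysis and hypoxia (0.691) 1 that fell, Slc16a3, both at limma adjusted p = 0.0499; adjusted over the list alone 2 were higher in the former and 2 lower in the latter. Glucocorticoid response (0.405) held 0 genes past the threshold over all genes and 1 higher and 2 lower adjusted over the list alone. Oxidative phosphorylation (0.301), heat shock (0.593), cell cycle (0.754) and ribosomal proteins (0.0518) held 0 by either count. Ribosomal proteins passed as a list in 4 of the 9 fits that left out an array, with array weights, with the mean of a gene's probe sets and with repeated quantile normalization (0.00478). Of the 10 marker lists 0 passed, although the monocyte marker Fn1 was higher (2 of 8 adjusted over the list alone) and the neutrophil marker Csf3r lower (3 higher and 1 lower of 10 adjusted over the list alone). Of the dendritic cell markers 1 of 9 was higher adjusted over the list alone.

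Without control replicate 3, 204 genes passed in place of 326. Calls lost in at least 1 of the fits that left out an array were those of Cxcr4, Ifitm1, Cd101, Cybb, Oasl2 and Traf6 (highest limma adjusted p from 0.0623 to 0.121) without control replicate 3, of Lipa, Itga4 and Cyba without control replicate 2 (0.0625 to 0.126), and of Birc3, Bhlhe40, Dusp16, Casp4, Il1rn, Slc16a3, Dusp6, Ctsc, Prr5l and Rasa3 without activated replicate 2 (0.0554 to 0.167), each named at its highest value. Slc16a3 kept its call in 1 of the 9 fits, Bhlhe40, Birc3, Cyba, Dusp16, Itga4 and Oasl2 in 2, and Casp4, Cybb and Traf6 in 3. The others of these genes kept theirs in 4 to 7. The replicate block also removed the calls of Birc3, Casp4, Cd101, Cyba, Dusp16, Ifitm1, Il1rn, Itga4, Oasl2, Rasa3, Slc16a3 and Traf6, repeated quantile normalization those of Birc3 and Bhlhe40, and centring of arrays that of Birc3. The immediate early list kept its call in 4 of the 9 fits that left out an array and the chemoattractant receptor list in 5; both lost it under each filter on dim genes (adjusted p up to 0.127), and the latter also with repeated quantile normalization and the replicate block.

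**Figure D2:**
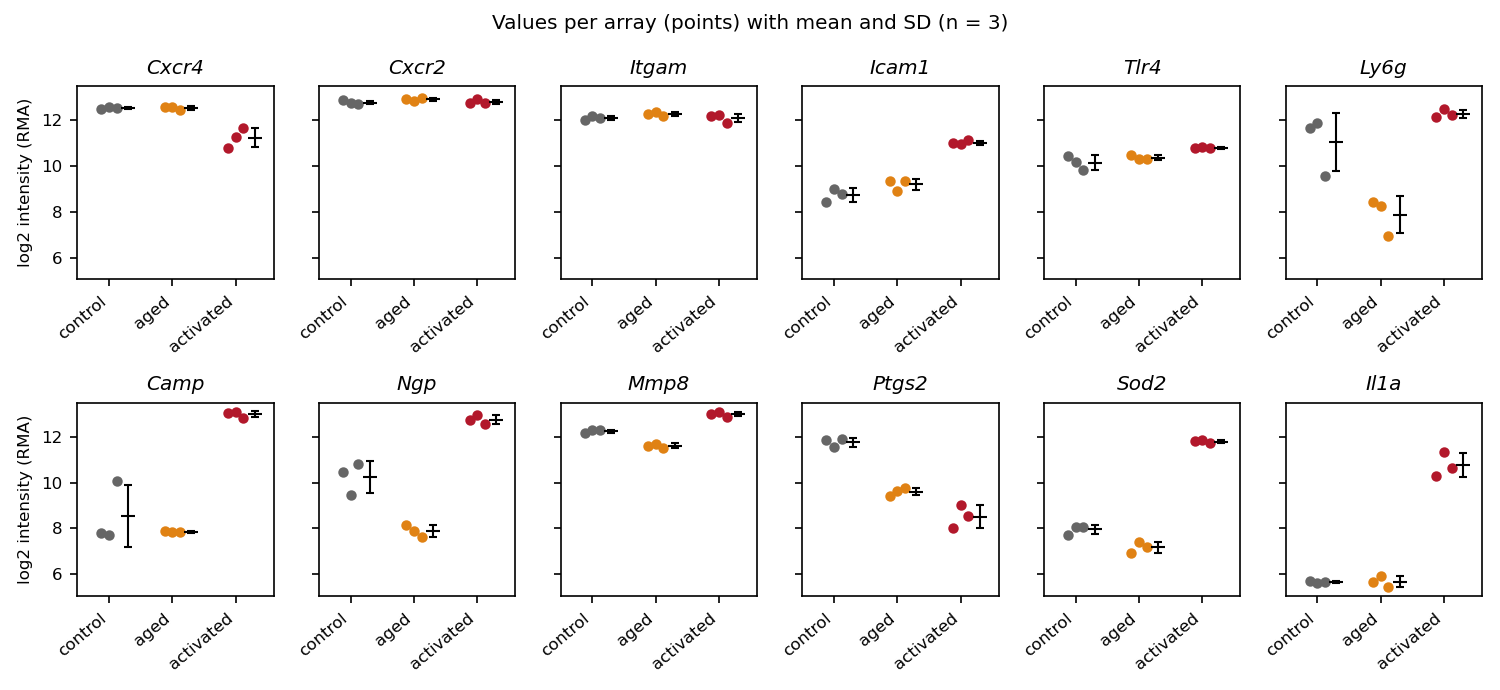
Log2 intensity (y axis) of 12 genes on each array (points), by group, with mean and SD (n = 3). Camp, Sod2 and Il1a were higher and Ptgs2 and Cxcr4 lower on every activated array than on every control array, while the control arrays of Ly6g spread widely.

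**Figure D3:**
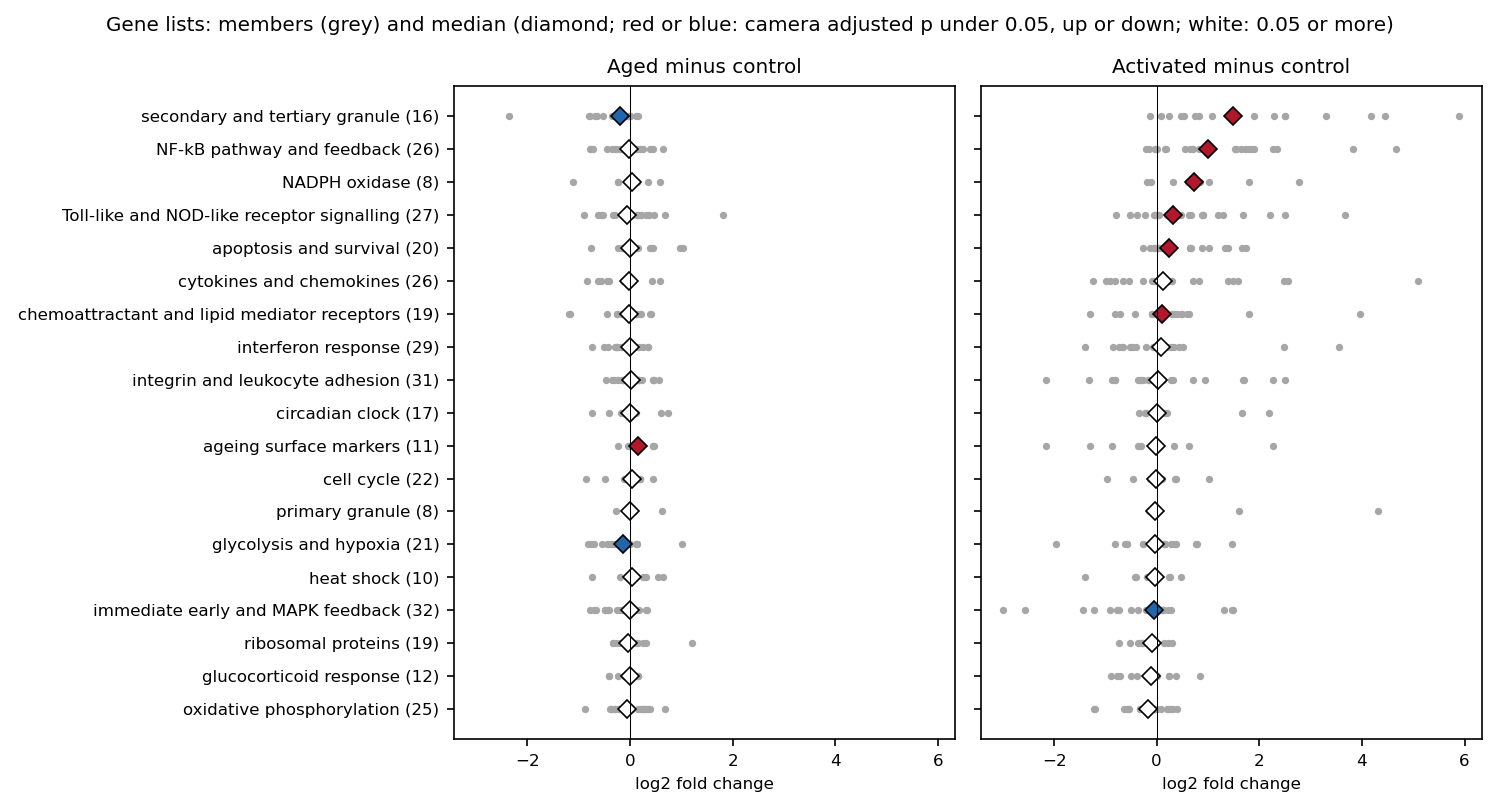
Log2 fold changes (x axis) of the members of 19 gene lists (grey points, number measured in parentheses) with the list's median (diamond, coloured where camera's adjusted p was under 0.05), for aged and activated against control. Granule genes had a median of -0.19 in aged cells, and 15 of 16 lay above 0 in activated cells.

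The third comparison set activated directly against aged neutrophils; since the aged cells had been transferred 6 h before and a transfer of the activated cells is not stated, TNF and transfer cannot be told apart in its values either. Among granule transcripts, Camp was at least 34.1-fold, Chil3 at least 23.6-fold and Ltf at least 17.9-fold higher in activated cells, with aged means under the receptor level, and Ngp was 28.7-fold higher (95% interval 16.9 to 48.9, n = 3 per group). Aged replicate 3 of Ngp lay under that level too, so its fold is measured partly against background. Sod2 was at least 15.1-fold, Ggh, a lysosomal hydrolase of folates, at least 13.1-fold and the cytokine Il1a at least 7.37-fold higher. Among the lowest in activated cells were Gngt2, a G protein subunit (log2 fold change -3.07 ± 0.35), Lipa (-2.97 ± 0.40), Fgl2 (-2.74 ± 0.19) and Gm2a, a lysosomal activator protein (-2.70 ± 0.16). Tas2r143 was at least 6.83-fold and Coq10b at least 4.02-fold lower, with activated means under the receptor level. Gngt2 and Lipa each had an activated array under it, so their sizes are measured partly against background. In all 412 genes passed limma's threshold after Benjamini-Hochberg adjustment, 285 higher and 127 lower in activated cells.

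Granule genes (11 of 16 higher, 14 adjusted over the list alone) and NF-kB genes (12 of 26, 16 adjusted over the list alone) were higher, at camera adjusted p = 1.23e-25 and 3.54e-23, both with adjusted p = 0.000536 with an estimated correlation. Toll-like and NOD-like receptor genes were higher (4 of 27, 10 adjusted over the list alone; adjusted p = 5.02e-06, and 0.0129 with an estimated correlation). NADPH oxidase (1 of 8, 3 adjusted over the list alone), cytokines (4 higher and 2 lower of 26, 8 and 4 adjusted over the list alone) and chemoattractant receptors (3 and 1 of 19, 6 and 2 adjusted over the list alone) passed at 0.00221, 0.00794 and 0.0125. With an estimated correlation these 3 had adjusted p = 0.0701, 0.0767 and 0.137. Chemoattractant receptors also lost their call under each filter on dim genes (adjusted p up to 0.116) and without activated replicate 2 (0.206), and cytokines without the genes below the median intensity (0.39). The neutrophil marker list was higher too (camera adjusted p = 0.00622, and adjusted p = 0.19 with an estimated correlation). In it Ly6g, Il1r2 and Retnlg were higher and Csf3r lower (4 and 1 of 10 adjusted over the list alone). Ly6g was 21.1-fold higher, measured partly against background, since aged replicate 3 lay under the receptor level. The list lost its call without activated replicate 2 (0.08). The 9 marker lists of other cell types did not pass. Among them 1 of 8 monocyte markers (Fn1) and 1 of 9 dendritic cell markers (Cd74) were higher over all genes, and 2 and 1 adjusted over the list alone.

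The other 13 functional lists did not pass between activated and aged cells, with camera adjusted p from 0.0513 (apoptosis and survival) to 0.983 (adhesion). Within them, Icam1 was higher and Cxcr4, Itga4 and Itgax were lower among the ageing markers (1 and 3 of 11 adjusted over the list alone). Gadd45b was higher and Atf3, Fos and Dusp6 were lower among immediate early genes (3 and 4 of 32 adjusted over the list alone). Over all genes and adjusted over the list alone, adhesion had 6 higher and 3 lower and 6 and 6 of 31, interferon response 1 and 2 and 3 and 2 of 29, and glucocorticoid response 1 and 0 and 2 and 4 of 12. Apoptosis and survival had 2 higher and 4 adjusted over the list alone of 20, primary granules 2 and 2 of 8, and the other 6 lists 0 by either count. With repeated quantile normalization 3 of the 13 lists were lower past the threshold, ageing markers (0.0135), ribosomal proteins (0.0135) and immediate early genes (0.0449). The ageing markers also passed without activated replicate 2 (0.0128), and apoptosis and survival in 4 of the 9 fits that left out an array. Calls lost without activated replicate 2 included those of Atf3, Birc3, Ctsc, Cxcr4, Dusp6, Il1r2, Prr5l, Ptafr, Tas2r135 and Tlr2 (limma adjusted p from 0.0569 to 0.157). Oasl2 and Cd101 lost theirs without aged replicate 1 (0.0625 and 0.0786). Atf3 and Traf6 kept their calls in 1 of the 9 fits that left out an array, Gadd45b in 6 and Ptafr in 0. The replicate block removed the calls of Atf3, Birc3, Ccrl2, Cd101, Gadd45b, Ifitm1, Ptafr, Tlr2 and Traf6. Array weights removed that of Traf6, and repeated quantile normalization and centring of arrays that of Ptafr. A fit of only the compared groups gave 250 genes, as did the fit without activated replicate 2.

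A further comparison asked whether aged and activated cells changed alike against control. Of the genes past limma's threshold, 0 were shared, since 0 passed in aged cells. Among the 205 genes higher in activated cells, 99 lay above 0 in aged cells, with a median of -0.01, and among the 121 lower in activated cells, 81 lay below 0, with a median of -0.14. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had r = 0.226 and rho = 0.283. Unchanged groups simulated against the same controls gave a mean r of 0.515. No gene was changed in the simulation, whereas the measured log2 fold changes had an SD of 0.418 in activated and 0.262 in aged cells. Changes in 1 group alone lower r, so the 2 values of r are not directly comparable. The covariance was 0.0248, against a simulated mean of 0.0283 (0.0248 to 0.0313 over 100 simulations), a difference of -0.0035.

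At an unadjusted p under 0.05 in both comparisons, 210 genes shared their direction, 59 higher and 151 lower. Simulated unchanged groups gave a mean of 432.2 (402 to 465 over 20 simulations), and independent lists would share 20 and 22. The simulation took each gene's spread within each group, estimated from 3 arrays, as exact, while limma pooled the groups. Such uneven spreads can raise the number of calls, so the lower observed count is not read as less sharing than chance gives. The 3 control arrays could not be split into sets of 2 or more each, so part of any excess over independence may come from the shared controls. Between the comparisons of activated cells with control and with aged cells, which share the activated arrays, 264 genes passed in both, all in the same direction.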

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

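The tests of rows without a single gene name were chosen after the main results were seen. Rows that name several genes or none were left out of the main comparisons and entered only the alternative with every row of the table, where a signal appeared in activated cells. By limma with adjustment over the rows, 10 of the 1275 rows that name several genes were higher in activated than in control neutrophils and 5 were lower. Of the 2050 rows that name no gene, 16 were higher and 1 was lower, with a largest log2 fold change of 4.97. Between aged and control neutrophils 0 rows of either kind passed. Which transcripts these rows measured was not analysed here.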

How the results depend on the processing

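The filter at the receptor level and the robust variance model were chosen after seeing the data. No result past the threshold changed direction under any alternative, while some lists that did not pass differed in direction between camera and fry. For aged against control, 6 genes passed without the genes below the median intensity and 6 with only genes brighter than the receptor level, where fewer genes were tested (Mmp8, Mynn, Nlk, Plk3 and Rfc2 lower, Ppp1r11 higher, named after their values were seen). Leaving out 1 array gave 0 to 3 genes, with 3 without control replicate 2 or aged replicate 3 and 1 without control replicate 3 or aged replicate 1, and the other alternatives gave 0. For activated against control, leaving out 1 array gave 204 to 322 genes, the lowest without control replicate 3, and the other alternatives 237 to 482. For activated against aged, 250 genes passed with only the 2 groups compared, and leaving out 1 array gave 250 to 353, the lowest without activated replicate 2, where fewer samples were fitted; the other alternatives except the block gave 382 to 592.

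The labels do not say that replicate numbers pair the samples. The deviations of same-numbered arrays from their group means correlated at 0.007 to 0.06 across genes, none over 0.1. Between differently numbered arrays of different groups they correlated at -0.04 to 0.014. In all, 9 of 9 arrays correlated best with their own number, a hint from the data and not from the design. A weak pairing is therefore not excluded. A replicate block gave 0 genes for aged against control, 237 for activated against control and 274 for activated against aged.

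With an estimated correlation 0 functional lists passed for aged against control, 3 for activated against control and 3 for activated against aged (granule, NF-kB, and Toll-like and NOD-like receptors in both). Fry gave 1, 9 and 9. Leaving out 1 array gave 1 to 3 lists for aged against control, 1 without aged replicate 2, and 5 to 8 and 6 to 7 lists for the others. The remaining alternatives gave 3, 5 to 8 and 4 to 9 lists, the 9 with repeated quantile normalization and the 4 without the genes below the median intensity. The correlation between the fold changes of aged and activated cells ran from 0.201 to 0.331 without 1 array, highest without control replicate 2, and the shared genes from 0 to 2, with 2 without control replicate 2. The cause of the changes was not tested apart from those named. Signal limits the dim genes: 40.6% of genes had a mean over the 9 arrays above the receptor level. Of the 326 genes called between activated and control cells, 315 had their highest group mean above it. That rule is easier to pass, so these shares are not directly comparable.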

Other observations

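The tests of the lysosomal list, of the granule and immediate early patterns and of the shared response were chosen after the results were seen; the other splits of the samples were planned. A lysosomal list of 34 measured genes, assembled because Lipa stood among the largest decreases, was lower in activated than in control neutrophils. Of its members 6 fell (Ctsa, Gla, Gm2a, Lipa, Npc1 and Ppt1, which break down proteins, glycolipids and lipids or export cholesterol) and 2 rose (the acid phosphatase Acp2 and the protease Ctsb). The median log2 fold change was -0.34, with camera p = 4.83e-07 and, adjusted by Benjamini-Hochberg, adjusted p = 4.99e-06, and adjusted p = 0.0224 with an estimated correlation. Against aged cells the adjusted p was 0.000229, and adjusted p = 0.0544 with an estimated correlation. Ggh, a lysosomal hydrolase that rose at least 12.9-fold against control, was not in the list; with it added the adjusted p was 0.000103, and adjusted p = 0.0443 with an estimated correlation, against control, and 0.0027 and 0.0927 against aged cells. In aged against control cells the list without it had a median of 0.02 and 0 genes past the threshold. A coordinated loss of lysosomal transcripts in activated cells is a hypothesis found and tested on the same arrays.

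The rise of granule transcripts in activated cells may reflect other cells in the sort or a change in which neutrophils circulate. Precursors at the promyelocyte stage would bring their primary granule transcripts. The 8 of that list had a median log2 fold change of -0.025 (SD 1.57), with Serpinb1a and Ctsc higher. The other 6 showed no rise, with a median of -0.05 (SD 0.065, highest 0.043), and their mean control log2 value of 7.2 lay under the receptor level. With members that rose and members that did not, the list as a whole leaves this open. Monocytes would raise their markers: the 5 that were dim in controls had a median of 0.431 (SD 0.26), the marker list passed camera only without activated replicate 3 (adjusted p = 0.0427), Csf1r had 0.31 and Ctss -0.43, against 2.49 for the 9 called granule genes, and the gate of the sort is not given in the labels. Younger neutrophils entering the blood remain open, since Cd101, which rises with maturation, fell by 2.80 (limma, adjusted p = 0.0185) while Cxcr2, which also does, had 0.032. Induction within the same cells by TNF also stays open, untested.

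The lower granule transcripts of aged cells did not rest on 1 array: the highest adjusted p over the 9 fits that left out an array was 0.00749 (camera). Fewer neutrophils among the sorted aged cells would raise the markers of the other cell types, but the highest median among their 9 lists was 0.032 (SD 0.04). The neutrophil markers themselves had a mean of -0.43 and a median of 0.00 (camera adjusted p = 0.123), with 4 of 10 lower adjusted over the list alone, and were lower past the threshold with repeated quantile normalization (0.00655) and without control replicate 3 (0.0263), so a change among the neutrophils is not excluded. A biological effect of time in the circulation is a hypothesis for this list, and the design cannot tell it apart from time since the handling of the transfer. The evidence is weak, at camera adjusted p = 0.125 with an estimated correlation and fry adjusted p = 0.0451. The estimated correlation was 0.01, equal to the preset, so it does not account for the higher camera p. Differences in amplification between groups were not tested.

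Immediate early genes could be lower in activated cells because the control cells had been transferred minutes before. The mean log2 fold change of the list was -0.224 against control, -0.112 for activated against aged cells and -0.112 for aged against control. The design has no untreated cells without transfer, so transfer and TNF cannot be told apart for this list.

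A response shared by aged and activated cells was looked for in the covariance of their fold changes, which at 0.0248 did not exceed the range simulated from the shared controls alone. A shared change in a small set of genes is not excluded by it.

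Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. For aged against control the real split gave 0 genes and the highest other 1, so all 10 gave as many. For activated against control the values were 326 and 2, and for activated against aged 412 and 0, with 1 split, the real one, reaching the count in each.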
